A study of Mus musculus with 8 samples.

How the data were processed

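Total RNA from the livers of male C57BL/6 mice aged 3 to 3.5 months was labelled with biotin and hybridised to 8 arrays, 4 from wild-type animals and 4 from animals without Amacr. Per the labels, each group held 4 biological replicates. Amacr encodes alpha-methylacyl-CoA racemase, an enzyme of peroxisomes and mitochondria needed for the side-chain shortening of bile acid intermediates and for the breakdown of branched-chain fatty acids. Per the labels' protocols, RNA was extracted with TRIzol. The deposited table held log2 values, 1 per probe set and array. RMA, a method that corrects the background, normalizes between arrays and summarises the probes of a probe set, is named in the submitters' processing notes without a version. The array type, the software, any filter and any batch step were not given in the sources used here. The deposited log2 values were written with 2 decimals, so differences near that step were rounded. RMA draws all arrays to a like distribution, so a shift of all genes in 1 direction would not be seen.

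The table held 16556 probe sets, of which 64 were controls of the array and were left out, leaving 16492 to be tested. The rule fixed beforehand spoke of all probe sets in the table; including the controls was therefore run as an alternative. The probe set IDs were Entrez gene numbers for 15250 probe sets. GEO's platform annotation named 1 gene for 15270 probe sets, several for 0 and none for 1222, and all 15270 named probe sets were matched by Entrez number to a RefSeq gene table (assembly GRCm38.p6). The table of genes served only for names, chromosomes and the order of neighbouring genes, because no genome build was given in the sources used here. The named probe sets covered 15267 genes, 3 of them with more than 1 probe set. For gene-level work the probe set with the highest mean over the 8 arrays stood for its gene. No 2 arrays held identical values. The table held no detection calls and no scan dates, so neither background nor batch was tested. The precision was set by the number of arrays, 4 against 4, and the median standard error of a difference was 0.09 on the log2 scale.

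Knockout and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, genotype as the only term, all 8 arrays, two-sided). P-values were adjusted by the Benjamini-Hochberg method over the 16492 probe sets, with a threshold of 0.05 on the adjusted p. A second count required in addition a log2 difference of at least 1, which is 2-fold. Every adjusted p of a gene below is from this limma fit. Single values also received an exact two-sided permutation test, for which 4 arrays against 4 cannot give a p below 0.0286.

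There were 34 gene lists, fixed with 690 entries of which 576 were measured. They covered bile acid synthesis, transport and sensing, cholesterol synthesis, fatty acid synthesis, peroxisomal and mitochondrial oxidation, PPAR-alpha targets, xenobiotic P450 genes, sulfation and glucuronidation, NRF2 and glutathione genes, glucose metabolism, and lipoprotein and cholesterol transport. Others covered male-biased and female-biased liver genes, the circadian clock, the interferon response, the acute phase, the unfolded protein response, heat shock, immediate early genes and the cell cycle. Marker lists covered pericentral and periportal hepatocytes, Kupffer cells, sinusoidal endothelium, stellate cells and fibroblasts, cholangiocytes, lymphocytes, neutrophils, erythroid cells, exocrine pancreas and adipocytes, and the last list held genes flanking Amacr on chromosome 15. Lists were tested with camera at a preset inter-gene correlation of 0.01, which compares the genes of a list with all other genes, and adjusted over the 34 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction, were alternatives. For each list the limma p-values were also adjusted over the list alone. Amacr was in no list.

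Genes were named by 3 rules. These took up to 12 of the largest rises and 12 of the largest falls among genes past the threshold whose groups did not overlap, up to 4 past the threshold from each list, and a fixed set of genes of bile acid, cholesterol and P450 metabolism whatever their p. Some genes of that set, among them Scp2 and Hmgcs1, were not analysed here. Other genes named below, among them those that passed only when adjusted over a list alone, were chosen after their values were seen.

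The steps were tested on simulated data with the mean of each of the 16492 probe sets over the knockout and wild-type arrays and its moderated variance, drawn independently for each probe set, so that genes did not vary together and 1 variance served both groups. In 10 runs, 61.8% of probe sets changed by 0.5 on the log2 scale were recovered, 94.3% of those changed by 1 and 99.2% of those changed by 2, and 5.71% of all calls were wrong. A simulated list of 20 genes shifted by 0.5 was found in 10 of 10 runs at an unadjusted p under 0.05, and an unshifted list in 0 of 10.

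Alternatives were quantile normalization of the deposited values, centring each array on its median, array quality weights, the replicate number as a block, leaving out the 33.3% of probe sets with the lowest mean, eBayes with trend and robust settings, the mean of the probe sets of a gene, adjusted p thresholds of 0.01 and 0.1, and leaving out each array in turn. Leaving out knockout replicate 2 together with wild-type replicate 4, and including the control probe sets, were chosen after seeing the data. Groups, tests, lists and the other alternatives were fixed before the data were examined.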

Results

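Liver expression was compared between wild-type mice and mice lacking Amacr, to see how the liver transcriptome differs when a step of bile acid synthesis is missing. Each group had 4 arrays, which per the labels are biological replicates. The array medians lay between 6.62 and 6.66 on the log2 scale. Values of 2 wild-type arrays correlated across probe sets with r from 0.9919 to 0.9962, and those of 2 knockout arrays with r from 0.9782 to 0.9945. Knockout replicate 2 stood apart from the rest. It had the lowest array quality weight, 0.2998 against 0.9349 to 1.753 for the other arrays. The other knockout arrays also differed from each other. On the first principal component, the main axis of variation between arrays (35.3%), knockout replicates 3 and 4 lay at 23.25 and 19.2. Replicate 2 lay at -34.47, and replicate 1, at -4.028, lay among the wild-type arrays, from -6.366 to 2.558. Medians of the NRF2 and clock lists below likewise set replicates 1 and 2 apart from replicates 3 and 4. The second principal component (25.7%) set the genotypes apart, with wild-type arrays from 11.94 to 15.36 and knockout arrays from -18.59 to -7.24. Knockout replicate 1, at -7.24, lay nearest to wild type on it. The median SD of a probe set was 0.11 in wild type and 0.14 in knockout.

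Amacr was lower in every knockout array. Its mean was 11.96 ± 0.18 (SD, n = 4) in wild type and 5.40 ± 0.13 (SD, n = 4) in knockout, a log2 difference of -6.55 (SE 0.10, limma adjusted p = 4.91e-09), or 93.9-fold lower in signal. How much of the knockout signal is background was not tested, so that fold is of the signals and not of the transcript. The wild-type mean lay at percentile 97.6 of all probe set means and the knockout mean at percentile 28.2. The values went with the genotype labels in all 8 arrays.

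Beside Amacr, few probe sets passed the threshold. In all, 19 of 16492 changed at an adjusted p under 0.05, 12 higher and 7 lower in knockout, and 5 of them by at least 2-fold, 4 higher and 1 lower. At an unadjusted p under 0.05 there were 1863, where chance gives 825. The groups did not overlap for 1100 probe sets, 6.67% of all, where chance gives 2.857%, and for all 19 that passed. The count was 2 without wild-type replicate 1, 3 without wild-type replicate 2, 3 without wild-type replicate 3 and 11 without wild-type replicate 4. It was 8 without knockout replicate 1, 7 without knockout replicate 3 and 5 without knockout replicate 4, and 39 without knockout replicate 2. The count at 2-fold was 2 without wild-type replicate 1, 2 or 3 and 6 without wild-type replicate 4, and 4, 11, 4 and 3 without knockout replicates 1, 2, 3 and 4.

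The largest rise among the genes past the threshold was that of Insig2, which holds the sterol-regulated transcription factors in the endoplasmic reticulum. Insig2 rose from 9.73 ± 0.14 to 11.16 ± 0.31 (SD, n = 4 each), a log2 difference of 1.43 (SE 0.15, limma adjusted p = 0.0144) or 2.69-fold. Elovl3, an elongase of very long-chain fatty acids, rose from 10.54 ± 0.41 to 11.87 ± 0.13 (SD), 2.51-fold (adjusted p = 0.0457). Its call was lost whichever single array was left out, with adjusted p from 0.0537 to 0.1497. The other calls at 2-fold were both unnamed clones, 9130409I23Rik, with a log2 difference of 1.27 (adjusted p = 0.00171), and 1810046K07Rik, with 1.15 (adjusted p = 0.0150). Smaller rises passed for Sgk2 (1.77-fold), Ethe1, a mitochondrial sulfur dioxygenase (1.69-fold), Zmat1 (1.62-fold), Nsdhl, an enzyme of cholesterol synthesis (1.56-fold), Taf1b (1.53-fold), Pvt1 (1.49-fold), Rbpms (1.46-fold) and Prkca (1.37-fold). As for Elovl3, the calls of Zmat1 and Pvt1 were lost whichever single array was left out.

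Besides Amacr, falls passed for Efhd2, from 11.39 ± 0.05 to 10.57 ± 0.14 (SD, n = 4 each, limma adjusted p = 0.0101), and for Ung, a uracil-DNA glycosylase, with a log2 difference of -0.81 (SE 0.11, adjusted p = 0.0400). Inhbc, an inhibin subunit made in the liver, had a log2 difference of -0.67 (adjusted p = 0.0402), Bin1 of -0.56 (adjusted p = 0.0358) and Slc9a3r1 of -0.49 (adjusted p = 0.0493), whose call was lost whichever single array was left out. The remaining call was an unnamed probe set. Of the 17 named calls other than Amacr, 1 passed without wild-type replicate 1, 1 without wild-type replicate 2, 1 without wild-type replicate 3 and 6 without wild-type replicate 4. Among the knockout arrays, 5 passed without replicate 1, 13 without replicate 2, 4 without replicate 3 and 3 without replicate 4. The sign was the same for all 17 in each of these. The clone 9130409I23Rik passed whichever single array was left out, and Insig2 did not pass without wild-type replicate 1, 2 or 3, its adjusted p over 16 alternatives ranging from 0.00815 to 0.140.

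Of 17 measured genes of bile acid synthesis, 0 passed over all genes and 1, Acox2, passed when adjusted over the list alone. Without wild-type replicate 4, 1 gene was lower over the list alone, and without that array and knockout replicate 2 together 2 were higher and 2 lower. Acox2, the peroxisomal oxidase that acts on the bile acid side chain after Amacr, was 11.10 ± 0.11 in wild type and 11.77 ± 0.28 in knockout (SD, n = 4 each), a log2 difference of 0.67 (SE 0.13, limma adjusted p = 0.116 over all genes and 0.0108 over the list alone), higher in 4 of 4 knockout arrays than in any wild-type array. Cyp7a1, the rate-limiting enzyme of the classic pathway, differed by -0.19 (SE 0.33, adjusted p = 0.864), less than its spread between wild-type arrays of 0.63 (SD). It was 10.37 in wild-type replicate 4 against 11.45 to 11.72 in the other wild-type arrays. In knockout replicate 2 it was 11.72 against 10.65 to 11.36 in the other knockout arrays. Without wild-type replicate 4 the Cyp7a1 difference was -0.50, and its limma adjusted p over 16 alternatives ranged from 0.152 to 0.985. For Cyp8b1, the sterol 12-alpha-hydroxylase, the difference was 0.56 (SE 0.23, adjusted p = 0.416). The largest difference in the list was that of Cyp39a1, an oxysterol hydroxylase, at -1.24 (SE 0.40, adjusted p = 0.298 over all genes and 0.0711 over the list alone). The other enzymes fixed beforehand lay closer to 0: Cyp27a1 at 0.07 (SE 0.08), Cyp7b1 at -0.13 (SE 0.46), Hsd17b4 at 0.09 (SE 0.08), Slc27a5 at 0.01 (SE 0.08) and Baat at -0.12 (SE 0.08), none with an adjusted p under 0.05. In knockout replicate 2, Cyp7b1 was 10.83 against 12.30 to 13.06 in the other knockout arrays. The list as a whole was not called (median log2 difference 0.01, camera adjusted p = 0.564).

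Among 15 bile acid transporters, 0 passed over all genes and 4 were higher when adjusted over the list alone. These were Abcb11, the canalicular bile salt export pump (log2 difference 0.45, SE 0.14, 0.0335 over the list alone), Abcg2 (0.35, SE 0.08), Slc51b (0.64, SE 0.16) and Abcb4 (0.37, SE 0.10). That count was 3, 1, 3 and 2 without wild-type replicates 1, 2, 3 and 4, was 2, 2, 4 and 5 without knockout replicates 1, 2, 3 and 4, and was 0 without knockout replicate 2 and wild-type replicate 4 together. Slc10a1, the sodium-dependent uptake transporter, differed by -0.23 (SE 0.14, adjusted p = 0.567). The transport list was not called (camera adjusted p = 0.336).

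Of 13 genes of bile acid sensing, 9 had lower means in knockout, 0 passed over all genes and 3 were lower when adjusted over the list alone. The bile acid receptor Nr1h4 went from 10.42 ± 0.07 to 9.93 ± 0.22 (SD, n = 4 each; log2 difference -0.49, SE 0.11, limma adjusted p = 0.136), and its target Nr0b2 differed by -0.58 (SE 0.16, adjusted p = 0.224). Ppara differed by -0.63 (SE 0.12, adjusted p = 0.116). All 3 were lower in each knockout array than in any wild-type array. The list shifted down (median -0.21, camera adjusted p = 0.00112, but adjusted p = 0.414 with an estimated correlation), and its mean gave the smallest exact permutation p possible, 0.0286.

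**Figure D1:**
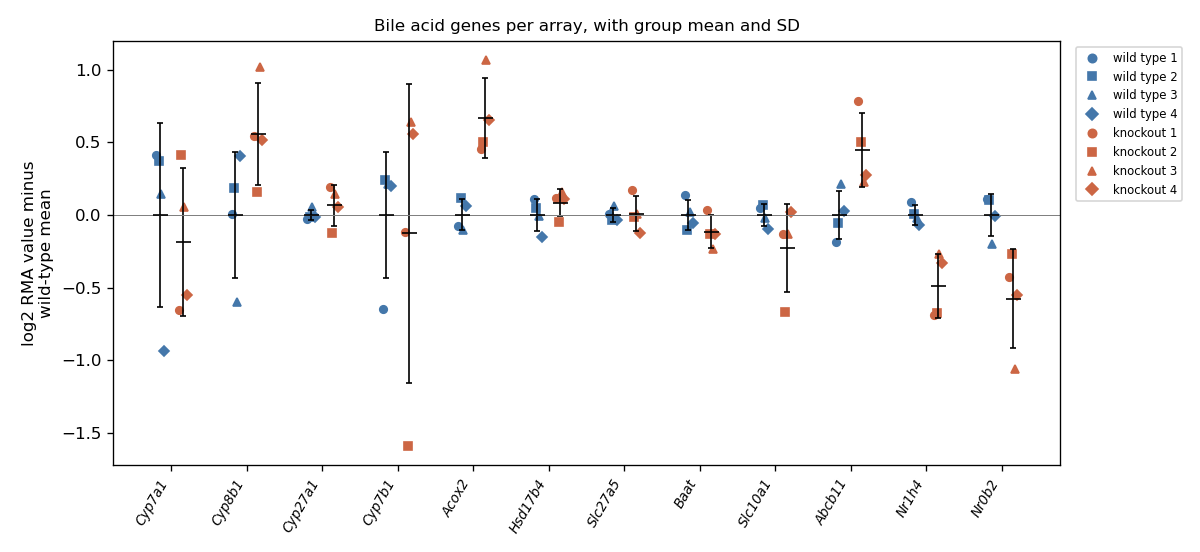
Log2 values of 12 bile acid genes, each minus its wild-type mean, per array (blue, 4 wild-type; orange, 4 knockout); black bars are group means with SD. The knockout points of Acox2 and Abcb11 lie above, and those of Nr1h4 and Nr0b2 below, all wild-type points, while those of Cyp7a1 overlap with a log2 difference of -0.19.

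Genes of cholesterol synthesis shifted up as a list at the preset correlation (camera adjusted p = 1.14e-08), but the call was lost with an estimated correlation (adjusted p = 0.549) and by fry (adjusted p = 0.127). Of 17 measured, 15 had higher means, 1, Nsdhl, passed over all genes, and 10 were higher and 0 lower when adjusted over the list alone. Nsdhl rose from 10.96 ± 0.07 to 11.61 ± 0.14 (SD, n = 4 each; log2 difference 0.65, SE 0.08, limma adjusted p = 0.0357). Mvk, mevalonate kinase, differed by 0.58 (SE 0.09, adjusted p = 0.0608), Hsd17b7 by 0.53 (SE 0.08, adjusted p = 0.0597), Dhcr7, the last reductase of the pathway, by 0.88 (SE 0.22, adjusted p = 0.179), and Lss, lanosterol synthase, by 0.89 (SE 0.27, adjusted p = 0.262). The other 5 were Pmvk, Cyp51, Tm7sf2, Msmo1 and Ebp. Sqle differed by 0.33 (SE 0.21, adjusted p = 0.586) and Srebf2 by 0.24 (SE 0.11, adjusted p = 0.462). Insig1 and Stard4 had lower means in knockout, and 1 of these 2 was lower in every knockout array than in any wild-type array. In the other direction, 8 of the 17 genes were higher in every knockout array than in any wild-type array.

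The list had a median log2 difference of 0.54, and the estimated correlation between its genes was 0.589. Its mean gave the smallest exact permutation p possible, 0.0286. The list median relative to the wild-type mean was 0.45 in knockout replicate 1, 0.81 in replicate 2, 0.20 in replicate 3 and 0.45 in replicate 4, against -0.04 to 0.03 in the wild-type arrays. In knockout replicate 2, 15 of the 17 genes had their highest value of all arrays. Without that array and wild-type replicate 4 together, 9 genes were higher when adjusted over the list alone and the camera adjusted p was 9.64e-05.

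**Figure D2:**
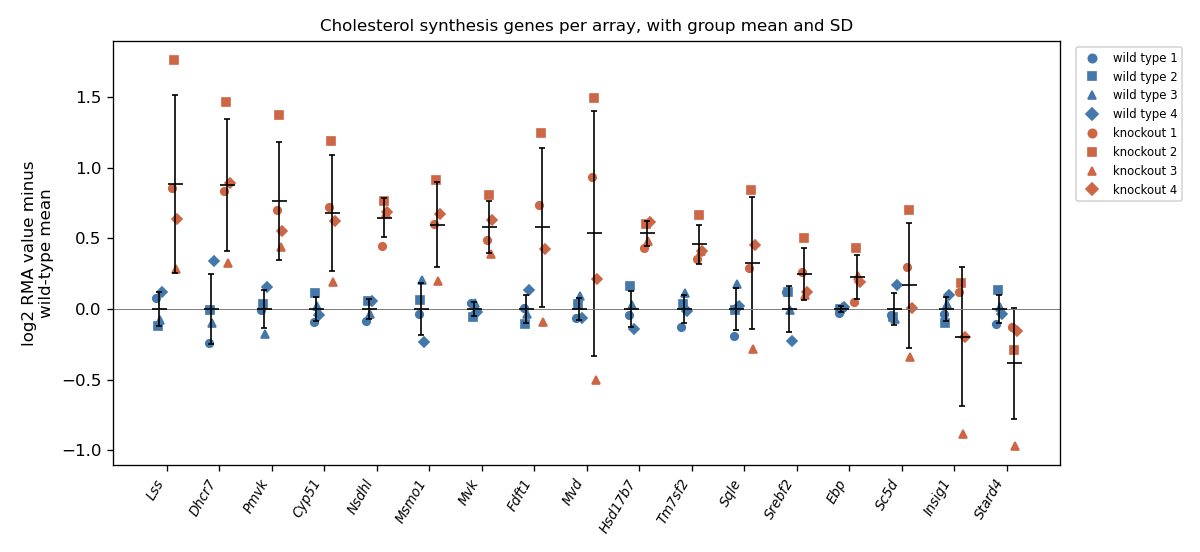
Log2 values of the 17 measured cholesterol synthesis genes, each minus its wild-type mean, per array (blue, 4 wild-type; orange, 4 knockout), ordered by log2 difference; black bars are group means with SD. Knockout replicate 2 (orange squares) is the highest point for 15 of the 17 genes, and Insig1 and Stard4 have lower means in knockout.

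Other lists of metabolism shifted as well at the preset correlation. The NRF2 and glutathione list, which holds detoxifying enzymes, shifted up (median 0.17, camera adjusted p = 0.000111, adjusted p = 0.650 with an estimated correlation). Of 18 genes 0 passed over all genes and 3 were higher over the list alone, Gstm4 by 0.57 (SE 0.10), Ephx1 by 0.43 (SE 0.07) and Gsta2 by 0.91 (SE 0.21). Its median was 0.44 in knockout replicate 1 and 0.57 in replicate 2, but -0.01 in replicate 3 and 0.02 in replicate 4, and without replicate 2 the camera adjusted p was 0.0572. The count over the list alone was 6 without knockout replicate 3. PPAR-alpha targets, genes of fatty acid breakdown, shifted up (median 0.33, camera adjusted p = 0.0198, adjusted p = 0.708 with an estimated correlation). Of 20 genes 0 passed over all genes and 3 were higher over the list alone, Cd36 by 1.44 (SE 0.27), Ehhadh by 0.85 (SE 0.21) and Acot2 by 0.63 (SE 0.16). The list median was 0.23, 0.17, -0.09 and -0.20 in wild-type replicates 1 to 4 and 0.21, 0.32, 0.72 and 0.23 in knockout replicates 1 to 4, so the groups overlapped, and the list mean gave an exact permutation p of 0.229. The adjusted p of that list was 0.113 without wild-type replicate 3, 0.115 without wild-type replicate 4 and 0.158 without knockout replicate 3. The count over the list alone was 4, 3, 1 and 1 without wild-type replicates 1, 2, 3 and 4, 1, 2, 1 and 6 without knockout replicates 1, 2, 3 and 4, and 0 without knockout replicate 2 and wild-type replicate 4 together. Cyp4a10, a PPAR-alpha target, differed by 0.85 (SE 0.45, adjusted p = 0.511) and Cyp4a14 by 0.87 (SE 0.75, adjusted p = 0.691), with wild-type replicate 4 the lowest array for both.

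Genes of glucose metabolism shifted down (median -0.17, camera adjusted p = 0.000747, adjusted p = 0.504 with an estimated correlation). The list median was -0.24, -0.24, -0.16 and -0.01 in knockout replicates 1 to 4 against -0.09 to 0.08 in wild type, so replicate 4 lay inside the wild-type range, and the list mean gave an exact permutation p of 0.0571. Of 14, 0 passed over all genes and 3 were lower over the list alone: Pfkfb3, a regulator of glycolysis, by -1.32 (SE 0.21, adjusted p = 0.0603), Gys2, the glycogen synthase of liver, by -0.98 (SE 0.25), and G6pc, glucose-6-phosphatase, by -0.66 (SE 0.21). That count was 1 without each of wild-type replicates 1, 2 and 4 and knockout replicate 1. The fatty acid synthesis list was not called (median -0.07, camera adjusted p = 0.284), but of its 18 genes 2 were higher over the list alone, Insig2 and Acss2 (0.85, SE 0.21), and 4 were lower, Elovl6 (-1.16, SE 0.25), Srebf1 (-0.76, SE 0.18), Mlxipl (-0.32, SE 0.08) and Pklr (-0.85, SE 0.26). Without knockout replicate 2, where the list median was 0.34, 7 were lower and the list passed at the preset correlation, downwards (camera adjusted p = 0.0172). With all 8 arrays its adjusted p was 0.798 with an estimated correlation and 0.834 by fry. The circadian clock list shifted down (median -0.35, camera adjusted p = 0.0173, adjusted p = 0.607 with an estimated correlation). Of 18 clock genes 0 passed over all genes, while over the list alone Arntl was higher (1.28, SE 0.36), Bhlhe40 was lower (-0.63, SE 0.15), and Per2 was lower, from 7.57 ± 0.26 to 6.57 ± 0.49 (SD). Over the list alone, 0 were higher without any single wild-type array or knockout replicate 1, and 0 were lower without wild-type replicate 1, wild-type replicate 2 or knockout replicate 1, while 5 were lower without knockout replicate 3 or 4. Its median was -0.41 in knockout replicate 1 and -0.75 in replicate 2, against -0.01 in replicate 3 and -0.07 in replicate 4. The adjusted p of the clock list was 0.0822 without wild-type replicate 4 and 0.0619 without knockout replicate 2.

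Marker lists of cell types and zones were measured alongside. Interferon response genes shifted down (median -0.57, camera adjusted p = 2.22e-06, adjusted p = 0.614 with an estimated correlation), with 0 of 18 genes past the threshold over all genes and 0 over the list alone. Without knockout replicate 2 and wild-type replicate 4 together 4 were lower over the list alone. The median of that list was 0.89 in wild-type replicate 4 against -0.34 to -0.19 in the other wild-type arrays, and -0.24, -0.39, -0.95 and -0.91 in knockout replicates 1 to 4. Pericentral hepatocyte genes shifted down (median -0.18, camera adjusted p = 9.22e-05, adjusted p = 0.414 with an estimated correlation). Of 18, 0 passed over all genes and 2 were lower over the list alone, Slc1a2 by -0.93 (SE 0.22) and Gulo by -0.37 (SE 0.08). That count was 1, 0, 0 and 2 without wild-type replicates 1, 2, 3 and 4, and 3, 2, 0 and 2 without knockout replicates 1, 2, 3 and 4. Kupffer cell markers shifted down (median -0.37, camera adjusted p = 0.000801, adjusted p = 0.708 with an estimated correlation), with 0 of 17 past the threshold over all genes or over the list alone. Their median was -0.66 in knockout replicate 3 and -0.93 in replicate 4, 0.10 in replicate 1 and 0.07 in replicate 2, against wild-type medians from -0.45 in replicate 2 to 0.48 in replicate 4, where 13 of the 17 markers had their highest value of all arrays. The adjusted p was 0.0838 without wild-type replicate 4 and 0.0631 without knockout replicate 4.

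Lymphocyte markers shifted down (median -0.16, camera adjusted p = 0.0475, adjusted p = 0.754 with an estimated correlation). Of 14, 0 passed over all genes and 1, Jchain, was lower over the list alone, and Jchain was 10.53 in wild-type replicate 4 against 7.45 to 8.10 in the other wild-type arrays. Jchain no longer passed over the list alone without wild-type replicate 1 or 2 or knockout replicate 1, 3 or 4. Without wild-type replicate 4 the adjusted p of the lymphocyte list was 0.531, and it was 0.0569 without knockout replicate 2, 0.138 without knockout replicate 3 and 0.107 without knockout replicate 4. Cholangiocyte markers shifted up (median 0.16, camera adjusted p = 0.0429, adjusted p = 0.708 with an estimated correlation). Of 11, 0 passed over all genes and 1, Krt23, was higher over the list alone (log2 difference 1.47, SE 0.22, adjusted p = 0.0569). That count was 2 without knockout replicate 2 or knockout replicate 3. The signals were low, as 0 of the 11 markers had a wild-type mean above the median of all probe sets. The median of the cholangiocyte list was 0.81 in knockout replicate 2, and its adjusted p was 0.367 without that array, 0.0711 without knockout replicate 1, and 0.0788, 0.107 and 0.0658 without wild-type replicates 1, 2 and 3.

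**Figure D3:**
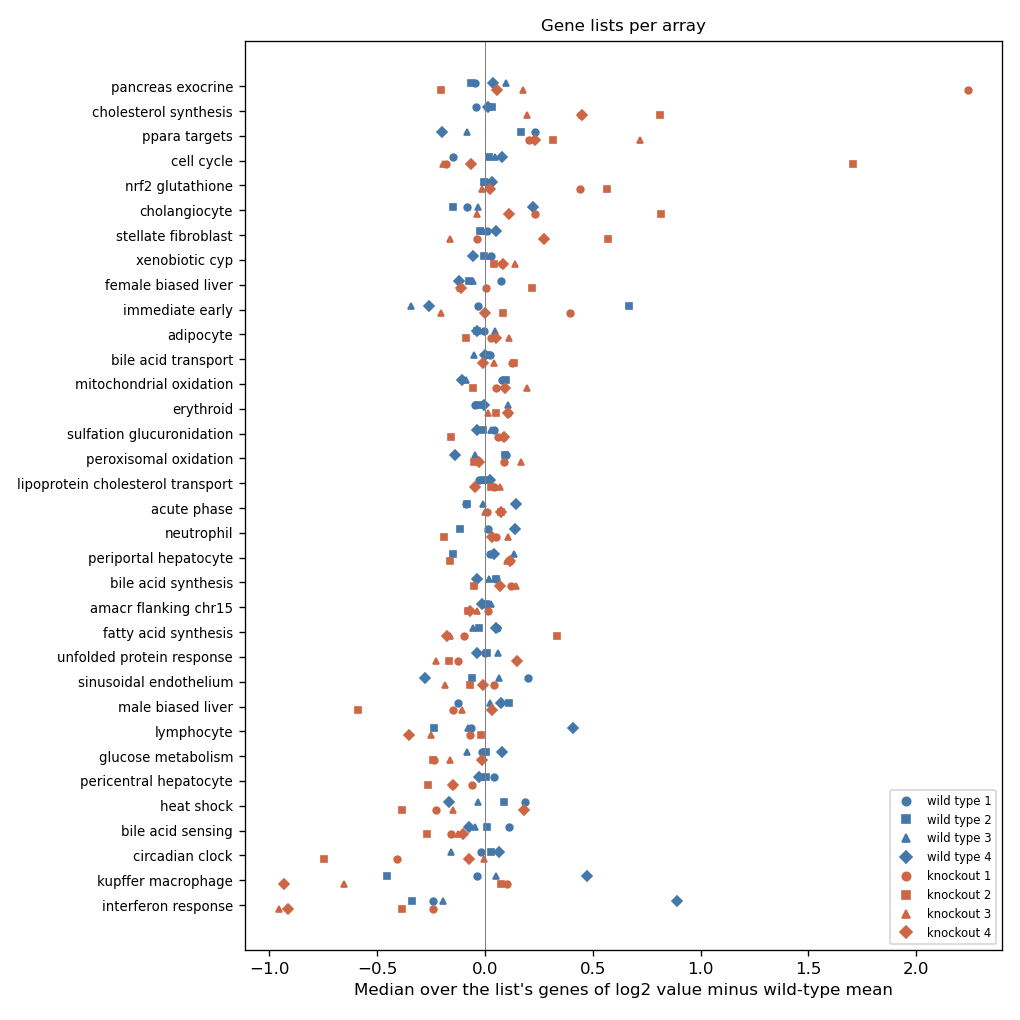
Median over the genes of each of the 34 lists of the log2 value minus the wild-type mean, per array (blue, 4 wild-type; orange, 4 knockout). The exocrine pancreas list stands at 2.24 in knockout replicate 1, the cell cycle list at 1.71 in knockout replicate 2, and the interferon response list at 0.89 in wild-type replicate 4.

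The other lists were not called. These were peroxisomal oxidation (median 0.04 but mean -0.02, camera adjusted p = 0.8003), mitochondrial oxidation (0.144), xenobiotic P450 genes (0.0965), sulfation and glucuronidation (0.669), lipoprotein and cholesterol transport (0.470), and male-biased (0.336) and female-biased genes (median 0.11 but mean -0.11, adjusted p = 0.981). Cyp3a11, a P450 gene fixed beforehand, differed by 0.14 (SE 0.08, adjusted p = 0.534). The camera adjusted p was 0.709 for the acute phase, 0.109 for the unfolded protein response, 0.135 for heat shock, 0.981 for immediate early genes and 0.103 for the cell cycle. For markers it was 0.470 for periportal hepatocytes, 0.236 for sinusoidal endothelium, 0.124 for stellate cells and fibroblasts, 0.981 for neutrophils (median 0.01 but mean -0.04), 0.144 for erythroid cells, 0.125 for exocrine pancreas and 0.340 for adipocytes. Over a list alone, higher genes in these lists were Acox2 and Ehhadh (peroxisomal), Cyp2b10 and Aldh1a7 (P450 genes), Ugdh (glucuronidation), Cyp4a12a and Elovl3 (male-biased), Orm3 and Il1rn (acute phase), Etnppl (periportal) and Alas2 (erythroid). Lower were Nudt7 (peroxisomal and male-biased), Fmo2 (female-biased) and Steap4 (acute phase).

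Many of these counts over a list alone changed when 1 array was left out. For xenobiotic P450 genes 0 were higher without any single wild-type array, and 1 without knockout replicate 1, 2 or 4. For the acute phase 0 were higher and 0 lower without wild-type replicate 1, 2 or 3 or knockout replicate 3, and 0 lower without knockout replicate 1 but 2 without knockout replicate 4. For periportal hepatocytes 0 were higher without wild-type replicate 2, 3 or 4 or knockout replicate 1 or 4, and 3 without knockout replicate 2. For erythroid cells 0 were higher without wild-type replicate 1 or 2 or knockout replicate 3. For female-biased genes 0 were lower without wild-type replicate 1 or 3 or knockout replicate 1 or 4, 2 without wild-type replicate 4 and 3 without knockout replicate 2. For peroxisomal oxidation 1 was higher without wild-type replicate 2, 3 or 4 or knockout replicate 1 or 3, and 2 were lower without knockout replicate 2. In lists with 0 over the list alone, 7 cell cycle genes were lower without knockout replicate 2 and 5 without that array and wild-type replicate 4 together, 2 heat shock genes were lower without knockout replicate 4, and 2 stellate cell and fibroblast genes were higher without knockout replicate 3. For male-biased genes 2 were lower without knockout replicate 4.

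Leaving out 1 array brought some of the lists that were not called past the threshold at the preset correlation. With all 8 arrays, the adjusted p of the lists named here was from 0.607 to 0.986 with an estimated correlation, which was not run with an array left out. Mitochondrial oxidation shifted up without wild-type replicate 1 (adjusted p = 0.0210) or 2 (0.0371), and immediate early genes up without wild-type replicate 2 (0.0216). Xenobiotic P450 genes shifted up without wild-type replicate 1 (0.0132), knockout replicate 3 (0.0378) or knockout replicate 4 (0.0320), and sinusoidal endothelium down without wild-type replicate 4 (0.00738). Without knockout replicate 3, stellate cells and fibroblasts (0.00267) and exocrine pancreas (0.0378) shifted up. Without knockout replicate 4, the unfolded protein response (6.08e-05) and heat shock (0.00165) shifted down and exocrine pancreas up (0.03503). The cell cycle list shifted up without knockout replicate 1 (0.00560), 3 (0.00387) or 4 (0.00745) and down without knockout replicate 2 (0.000222).

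In all, 11 of the 34 lists were called at the preset correlation, 4 up and 7 down, against 15 at an unadjusted p under 0.05. With an estimated correlation 0 were called, the lowest adjusted p being 0.414, and by fry 0. Of the 35 splits of the 8 arrays into 4 and 4, 22 gave at least as many called lists as the genotypes did. The smallest exact permutation p possible, 0.0286, not adjusted over the lists, was reached by 5 list means, among them the erythroid and flanking lists, which were not called. For called lists it was 0.286 for the interferon response, 0.229 for Kupffer cells, 0.171 for lymphocytes and 0.143 for the clock. It was 0.114 for NRF2 and glutathione and for cholangiocytes.

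Genes flanking Amacr on chromosome 15 were compared because DNA near a targeted gene can stem from another strain. Of 32 measured, 16 had higher and 16 lower means, 0 passed over all genes, and 3 were lower over the list alone: Zfr, a zinc finger RNA-binding protein, Npr3 and Sub1. Zfr went from 7.42 ± 0.26 to 6.43 ± 0.24 (SD, n = 4 each; log2 difference -0.99, SE 0.15, limma adjusted p = 0.0597), Npr3 differed by -0.32 (SE 0.08, adjusted p = 0.173) and Sub1 by -0.29 (SE 0.08, adjusted p = 0.192). The 3 genes were consecutive among the measured genes on that side of Amacr. The list had a camera adjusted p of 0.103 and a fry adjusted p of 0.0598, and its mean gave the smallest exact permutation p possible, 0.0286. The count over the list alone was 2 without wild-type replicate 4 and 1 without any other single array. Over all genes, Zfr passed in 6 of 16 alternatives, with adjusted p from 0.00566, without knockout replicate 2 and wild-type replicate 4 together, to 0.222, without wild-type replicate 2. Without wild-type replicate 4 alone it was 0.0429.

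**Figure D4:**
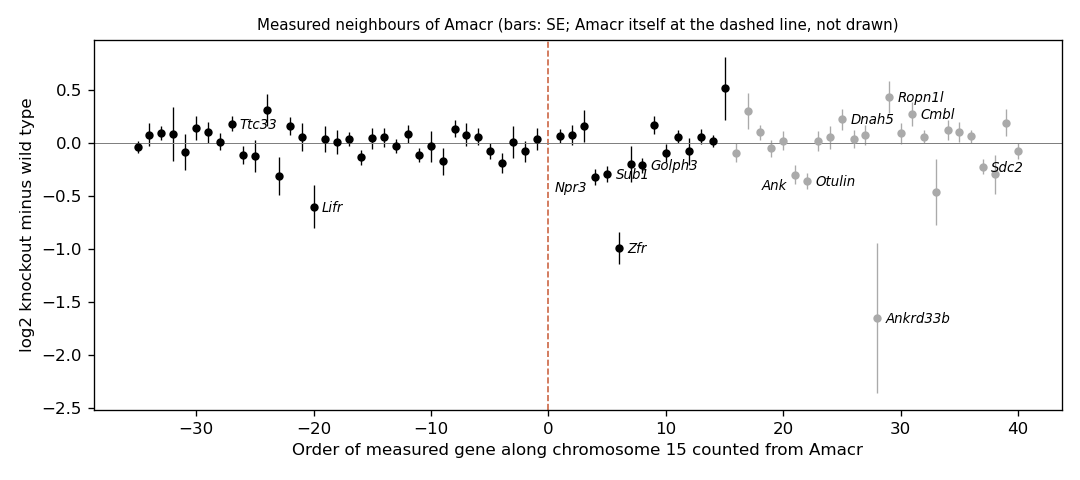
Log2 difference, knockout minus wild type, with its SE (bars) for measured genes on chromosome 15, in their order from Amacr (dashed line); black points lie within 10 Mb of Amacr, grey points farther, and names mark an unadjusted p under 0.05. Apart from Amacr itself, Zfr, at -0.99, lies lowest among the genes within 10 Mb, with Npr3 at -0.32 and Sub1 at -0.29 beside it.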

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

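The tests of knockout replicate 2, of the cholesterol genes, of runs of neighbouring genes and of the splits without Amacr were chosen only after the results were seen, and the count of called genes near Amacr and the other tests of splits were fixed earlier. An array was singled out where its gap to the nearest of the 4 of its group was large against the range of the group, which chance does in about 1 of 20 groups. Of 170 gene groups 6 were singled out, below the 5% that chance gives, and of 68 list groups 6, which is above it.

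Among genes, wild-type replicate 4 had the lowest Amacr of its group, 11.68 against 12.03 to 12.06. Ung was 7.33 in wild-type replicate 2 against 7.01 to 7.05, and Cyp27a1 was 12.79 in wild-type replicate 3 against 12.71 to 12.72. Cyp7b1 was 11.77 in wild-type replicate 1 against 12.62 to 12.66, and Abcg2 was 10.91 in knockout replicate 3 against 10.76 to 10.78. Zfr was 6.07 in knockout replicate 2 against 6.53 to 6.56, all lower than in the wild-type arrays.

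Among list medians, knockout replicate 2 stood out for the cell cycle, at 1.71 against -0.20 to -0.06 in the other knockout arrays, for fatty acid synthesis, at 0.34 against -0.18 to -0.10, for sulfation and glucuronidation, at -0.16 against 0.06 to 0.09, and for periportal hepatocyte genes, at -0.16 against 0.10 to 0.12. The interferon response list stood at 0.89 in wild-type replicate 4 against -0.34 to -0.19. The exocrine pancreas list stood at 2.24 in knockout replicate 1 against -0.20 to 0.18.

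Knockout replicate 2 differed from the other arrays in genes of cell division. All 23 measured cell cycle genes were highest there; Cdc20 was 9.69 against 4.40 to 5.11 in the other arrays, Birc5 8.25 and Cdk1 9.33. RNA degradation would raise the 3' over the 5' signal of control transcripts, but actin gave 0.47 on the log2 scale there and 0.46 to 0.64 in the other arrays, and Gapdh -0.20 against -0.22 to -0.10, which argues against it. More biliary cells stay open, since 7 of the 11 cholangiocyte markers were highest in that array, but Krt7, at 5.04 against 4.80 to 5.19, was not. This was not particular to biliary markers, since 12 of 18 stellate cell and fibroblast genes were also highest there. Growth or injury in that animal was not tested.

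The higher cholesterol synthesis genes do not rest on knockout replicate 2 alone, since the lowest list median of the other 3 knockout arrays was 0.20 against at most 0.03 in wild type. A different time of day at collection cannot be told apart from the genotype: of the 4 knockout arrays, all with a raised list median, 3 had Arntl above and Dbp below every wild-type array. Replicate 3 is among these by little, with Dbp at 11.13 against 11.17 in the lowest wild-type array, and in replicate 4, whose list median of 0.45 was like that of replicate 1, Dbp lay inside the wild-type range at 11.49. In replicates 3 and 4 Tef, at 9.80 and 9.70, also lay inside the wild-type range and Usp2, at 9.92 and 9.79, above it, where both were below it in replicates 1 and 2, while Arntl, at 5.95 and 5.74, lay above and Per2, at 6.97 and 7.01, below every wild-type array. Collection times were not given in the sources used here, and the loss of Amacr stays open as an untested cause. Since Arntl and Per2 set all 4 knockout arrays apart, the same limit holds for the other genes and lists besides Amacr. Insig2, Elovl3 and the glucose metabolism genes are among them.

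DNA of another strain kept around the targeted Amacr allele cannot be excluded or shown. Of 50 measured genes within 10 Mb of Amacr 0 passed the limma threshold, against 0.109% on other chromosomes (one-sided exact Fisher p = 1), while 5 were lower and 1 higher at an unadjusted p under 0.05. An interval of up to 7.11% keeps that test open. Among 13718 runs of 50 consecutive measured genes on other chromosomes, a share of 0.155 held at least 5 such lower genes. That share does not register how close together the lower genes lie. Npr3, Sub1, Zfr and Golph3 (-0.21, SE 0.07) were the measured genes at places 4, 5, 6 and 8 from Amacr. Each of these was lower in every knockout array than in any wild-type array. Lifr, the other lower gene, lay on the other side at place 20. Whether such a cluster arises by chance was not tested.

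The genotype split gave 19 probe sets past the threshold and 5 at 2-fold, and the highest of the other splits gave 0 and 0, so 1 of 35 splits gave as many. Amacr, the deleted gene, is in both counts and would alone have given that result, so it says nothing about the other calls. With Amacr left out of the fit and the adjustment, 15 of 16491 probe sets passed in the genotype split and 4 at 2-fold. The highest other split gave 0 and 0, again 1 of 35 for each, the lowest share that 35 splits can give. The genotype split thus gave more calls than any other split, but chance is not excluded for these counts or for any single gene. Nor can the splits tell the genotype apart from another condition shared by the knockout arrays. The count of called lists was 11 against 16 in the highest other split, with 22 of 35 splits at 11 or more, so chance cannot be excluded for the number of lists.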

How the results depend on the processing

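Leaving out knockout replicate 2 and wild-type replicate 4 together, and including the control probe sets, were chosen only after the results were seen. The Amacr difference kept its direction and passed in each alternative run for it, from -6.64 without wild-type replicate 4 to -6.50 without knockout replicate 4. The median difference of all probe sets was 0.02 in the deposited values, 0.0036 with quantile normalization and 0.0075 with centring on the median. Values in brackets below are adjusted p-values.

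The count of 19 probe sets past the threshold was 38 with quantile normalization (24 higher, 14 lower), 75 with array quality weights (41 higher, 34 lower), 33 without the 33.3% of probe sets with the lowest mean (19 higher, 14 lower) and 36 with trend and robust eBayes (24 higher, 12 lower). Of the 19, the same probe sets passed for 18, 19, 18 and 19 in these. It was 3 at an adjusted p under 0.01 (1 higher, 2 lower) and 64 at one under 0.1 (37 higher, 27 lower), and these follow from the thresholds. Centring gave 22 and including the controls 19, with all 19 shared, and the mean of the probe sets of a gene gave 18, all shared. Leaving out 1 array gave from 2 to 39 (1 to 21 higher, 1 to 18 lower). Leaving out knockout replicate 2 and wild-type replicate 4 together gave 39 (18 higher, 21 lower), of which 9 were shared. The count at 2-fold, 5, was 13 with array quality weights, 13 without those 2 arrays and from 2 to 11 when 1 array was left out.

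The replicate number as a block left 1 probe set, Amacr (0 higher, 1 lower), and 1 at 2-fold. Deviations of the arrays with a shared number from their group means correlated across probe sets with r = 0.0496, -0.0266, 0.0915 and -0.115 for numbers 1 to 4, and 3 of 8 arrays were closest to the array of their own number, so the numbers gave no sign of pairs. The block has fewer degrees of freedom, and the calls it ended say nothing about smaller differences.

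The number of called lists, 11, was 7 with array quality weights, 7 without knockout replicate 2 and wild-type replicate 4 together, and from 8 to 14 when 1 array was left out. With an estimated correlation it was 0, and by fry 0. The calls ended with an estimated correlation for bile acid sensing (0.414), cholesterol synthesis (0.549), PPAR-alpha targets (0.708), NRF2 and glutathione (0.650), glucose metabolism (0.504), clock (0.607), interferon response (0.614), pericentral hepatocytes (0.414), Kupffer cells (0.708), cholangiocytes (0.708) and lymphocytes (0.754). By fry the values in the same order were 0.127, 0.127, 0.357, 0.284, 0.161, 0.284, 0.357, 0.127, 0.575, 0.357 and 0.646. Fry's test for change in either direction was not used for calls, and it does not compare a list with other genes. Its adjusted p in that order was 0.000556, 0.00265, 0.0190, 0.0234, 0.00365, 0.0910, 0.176, 0.00365, 0.421, 0.0190 and 0.421. For lists not called it ran from 0.000429 (fatty acid synthesis, male-biased genes) to 0.760 (unfolded protein response), with 0.00195 for bile acid synthesis.

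Other calls ended for cholangiocytes with quantile normalization (0.0824), lymphocytes with centring (0.0582) and without the probe sets with the lowest mean (0.230), and cholangiocytes (0.0911) and lymphocytes (0.0638) with the block. With array quality weights those of PPAR-alpha targets (0.0508), clock (0.0627), cholangiocytes (0.173) and lymphocytes (0.0627) ended. Without knockout replicate 2 and wild-type replicate 4 together those of PPAR-alpha targets (0.121), NRF2 and glutathione (0.0620), glucose metabolism (0.0620), clock (0.162), cholangiocytes (0.137) and lymphocytes (0.162) ended, and sinusoidal endothelium came past the threshold, downwards (0.0141). The cell cycle list, with adjusted p from 0.000222 to 0.168 when 1 array was left out, shifted down instead of up without knockout replicate 2 (0.000222) and without that array and wild-type replicate 4 (0.00486); all 23 of its genes were highest in knockout replicate 2. For the other changes the cause was not tested.

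When 1 array was left out, the adjusted p ranged from 0.000454 to 0.0190 for bile acid sensing, 6.34e-15 to 4.10e-05 for cholesterol synthesis, 0.000752 to 0.158 for PPAR-alpha targets, 4.37e-08 to 0.0572 for NRF2 and glutathione, 6.08e-05 to 0.0233 for glucose metabolism and 0.00314 to 0.0822 for the clock. It ranged from 2.44e-08 to 0.000753 for the interferon response, 4.83e-06 to 0.00473 for pericentral hepatocytes, 8.29e-07 to 0.0838 for Kupffer cells, 0.000513 to 0.367 for cholangiocytes and 0.000917 to 0.531 for lymphocytes.

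Apart from leaving out 1 array, values of named genes kept their side of the threshold in 608 cases, came past it in 33 and lost it in 28, and none of them reversed past the threshold. Leaving out 1 array, they kept it in 565 cases, came past it in 5 and lost it in 102. Besides Amacr only 17 named genes were past the threshold with all arrays. Most cases that kept their side were thus of genes not past it, and only those 17 could lose it. Counts over a list alone stayed within 1.5 times in 435 cases and moved in 41, and in 448 and 96 when 1 array was left out. The table held no background measure, so how much of a low signal, such as that of Amacr in knockout at 5.40, is background was not tested, and differences between low signals are limited by it.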

Other observations

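Genes in this part were chosen only after their values were seen, and none of them passed the threshold. Some differed widely between knockout arrays. Moxd1, a monooxygenase-like gene, was 5.43, 4.06, 10.49 and 8.17 in knockout replicates 1 to 4, against 3.68 to 4.17 in wild type. Ctse was 6.80, 6.47, 10.66 and 9.46, against 6.45 to 6.65, and Gdpd3 was 5.34, 5.12, 8.94 and 9.62, against 4.99 to 5.28. Usp2, a clock-regulated protease, was 6.96, 6.44, 9.92 and 9.79, against 9.41 to 9.68. Cyp2c55 was 10.24, 11.50, 8.66 and 8.32, against 7.69 to 8.51.

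In knockout replicate 2, Scd2 was 12.24 against 5.32 to 6.45 in the other arrays, Afp, alpha-fetoprotein, 8.62 against 4.32 to 5.36, and Anxa13 9.33 against 4.64 to 6.16. In knockout replicate 1 the pancreas genes Clps and Ctrb1 were 8.42 and 8.33, against 4.04 to 4.46 and 5.47 to 5.88 in the other arrays. In wild-type replicate 4 the interferon-induced gene Igtp was 12.16 against 9.01 to 9.71 in the other arrays.

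Among genes whose groups did not overlap but which missed the threshold, large differences were those of Nrep at -1.84 (limma adjusted p = 0.0565), Tgm1 at -1.32 (0.0603), Fgl1 at -1.11 (0.0761), Omd at 1.06 (0.0597) and Mtnr1a at 1.45 (0.102).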
